A study of Mus musculus with 2 samples.

How the data were processed

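H3K9me3 ChIP-seq of embryonic day 10.5 mouse hindbrain was analysed from deposited peak lists. Per the labels, there were 2 biological replicates of 1 group, each a pool of hindbrains from male and female embryos of strain B6NCrl (69 embryos in replicate 1 and 51 in replicate 2), with library fragments of 300 to 500 bp. The labels name a control experiment as a possible control. Whether and how it entered the peak calls is not given in the sources used here.

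There were 4 lists in the narrowPeak layout, on the mm10 assembly per the labels. The authors deposited a peak list for each replicate, a list called on the reads of both replicates together, and a list of replicated peaks that, per the text files deposited with them, was derived from the other 3 lists. The aligner, the peak caller, its thresholds, the treatment of duplicate and multiply mapped reads and the rule for a replicated peak are not given in the sources used here. The deposited signal value of each peak is the authors' own and is used only to rank and describe peaks within a list. What it is relative to is not given. The deposited −log10 p and −log10 q values of each peak were used to rank peaks and for stricter thresholds. The smallest −log10 p was 2.02 in replicate 1 and 2.00 in replicate 2. By q-value, 41.7% of the peaks of replicate 1 and 39.4% of those of replicate 2 had q above 0.05, against 1.62% of the replicated peaks, so both single-replicate lists are permissive. The sequencing depth is unknown. A deeper library, a better enriched one or another control can each change the length of a peak list, and peak lists do not tell these apart.

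Genes came from GENCODE release M21 (Ensembl 96) on GRCm38, with 55413 genes on the 21 main chromosomes, 21938 of them protein-coding. Sequence came from the soft-masked GRCm38 reference. Peaks on unplaced and unlocalized scaffolds were counted but not tested. No filter for genome regions prone to false signal was applied to the deposited lists. Peak coordinates are 1-based. A gene's window was its body plus 2 kb upstream, the TSS was the annotated 5′ end of the gene, so that internal start sites of a gene count as intron or exon, and an overlap needed at least 1 base. Each base was put in the first class that applied among promoter, coding exon, UTR or noncoding exon, intron and intergenic. Promoters were the 2 kb on either side of the TSS of a protein-coding gene. The start of a noncoding gene did not by itself count as a promoter. A peak's class was that of most of its bases.

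The 12 gene lists, the rule for the genes named and the tests of the results section were fixed before the data were examined. The tests of the closing section are dated there, and some were chosen after the data were seen. All members of each list were found in the annotation. Named were the 4 members of each list with the highest signal value (all members for imprinted genes), the 10 protein-coding genes with the most bases under replicated peaks, the 10 replicated peaks with the highest signal value and the 5 widest domains. Other names in the account of a list are given to describe its count and were chosen after their values were seen.

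With 1 group there was no test between groups. The overlap of peaks with genes, classes, sequence and the other replicate was tested by circular rotation, a permutation test: the peaks of each chromosome were shifted together by a random distance within the span of the deposited peaks, 1000 times with a fixed seed, which keeps the widths and the clustering of peaks. Two-sided p-values have a minimum of 0.0020. They were adjusted by the Benjamini-Hochberg method over the 12 lists, the 5 annotation classes or the 3 sequence measures. A rotation p-value describes where the peaks of these libraries lie along the genome and not the spread among embryos. The last coding exon and the TSS of clustered Zfp genes were compared with an exact two-sided sign test and with rotations. Domains were replicated peaks at most 10 kb apart. On simulated data, 20 sets of once-rotated replicated peaks gave p under 0.05 in 6 of 240 tests of the 12 lists (2.50%). Peaks planted at 100 of 200 random protein-coding genes were detected in all 20 sets. The first check used the rotation of the test itself, so it cannot show that rotation is a fair null. The planted genes were not clustered, so power for the 12 lists was not measured.

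Alternatives fixed before the data were examined were each replicate's list alone (that is, without the other replicate), the pooled list, a −log10 q of at least 5, other merging distances, overlap of at least 50% of a peak, equal list lengths, autosomes only, a TSS window, at least 500 bases of peak, 10000 random gene lists matched on gene length, promoter windows of 1 and 5 kb, and all Zfp genes. The list of replicated peaks that overlap both replicates' own lists was added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.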

Results

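H3K9me3, the trimethylated form of lysine 9 on histone H3 and a mark of constitutive heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in mouse hindbrain at embryonic day 10.5. The hindbrain is the part of the neural tube that forms the cerebellum, pons and medulla. The samples formed 1 group of 2 biological replicates from strain B6NCrl, with male and female embryos pooled. Replicate 1 was made from 69 embryos and replicate 2 from 51. The design held no treated or control group, so the comparisons were those between the replicates, and those between the positions of the peaks and the genes, annotation classes and sequence of the mm10 genome. Read totals were not given in the sources used here, so the sequencing depth of each replicate is unknown and no interval that needs it is given.

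H3K9me3 peaks were most frequent on chromosome 7, which carries many clusters of zinc finger, vomeronasal and olfactory receptor genes. The list of replicated peaks held 63900 peaks over 28.4 Mb, with a median width of 331 bp and a range of 105 to 15340 bp. Chromosome 7 held 9932 of them (15.5%), or 70.0 peaks per Mb of called sequence against 25.6 over all autosomes. Chromosome 17 came next with 47.3 peaks per Mb, followed by chromosomes 19 (31.5), 13 (31.3) and 12 (30.9). Chromosome X had 12.4 peaks per Mb, and chromosome Y had 0.658 with 58 peaks in all. The ranking of chromosome 7 held in each replicate, with 170.004 peaks per Mb in replicate 1 and 96.5 in replicate 2.

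**Figure D1:**
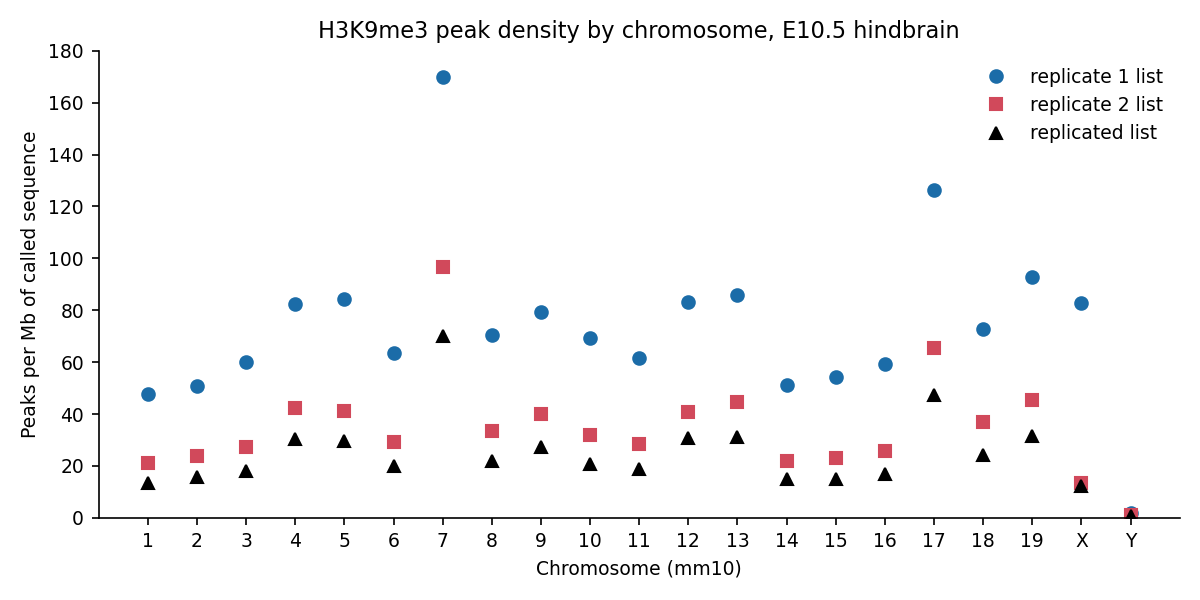
Peaks per Mb of called sequence (vertical axis) on each mm10 chromosome (horizontal axis) in the list of replicate 1 (circles), the list of replicate 2 (squares) and the replicated list (triangles). Chromosome 7 is highest in all 3 lists, and on chromosome X replicate 1 has 82.8 peaks per Mb while replicate 2 has 13.5.

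The replicates differed in the number of peaks. Replicate 1 had 195438 peaks over 42.7 Mb with a median width of 155 bp, and replicate 2 had 91746 peaks over 21.5 Mb with a median width of 172 bp. Peaks called on the pooled reads numbered 189725 and covered 48.3 Mb. On chromosome X the replicates differed more than elsewhere: replicate 1 had 13536 peaks there and replicate 2 had 2210, a ratio of 6.12, while the ratio ranged from 1.76 to 2.34 over the 19 autosomes.

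The strongest peaks were shared by the replicates and the weakest less often. Of the peaks of replicate 2, 62.8% overlapped a peak of replicate 1 by at least 1 base, against a mean of 3.84% and a highest value of 7.72% in 1000 rotations of the other list along each chromosome. In the other direction 28.6% of the peaks of replicate 1 overlapped one of replicate 2, against a rotation mean of 1.83%. Both shares lay outside all rotations (two-sided permutation test by rotation, p = 0.0020, the smallest that 1000 rotations can give). All of the 1000 peaks of replicate 2 with the smallest p-values overlapped a peak of replicate 1, and 99.7% of the top 1000 of replicate 1 overlapped one of replicate 2. Below rank 50000 the shares were 47.8% for replicate 2 and 18.4% for replicate 1. With the lists brought to equal length the shares moved to 48.4% and 43.9%.

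The replicated list was not the plain intersection of both replicates. All of its peaks had the same start and end as a pooled peak. Of these, 50041 (78.3%) overlapped a peak of both replicates, 11737 (18.4%) only one of replicate 1, 1943 only one of replicate 2, and 179 neither. The peaks that overlapped both replicates had a median −log10 q of 4.55, and the other 13859 had 2.89.

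Zinc finger genes of the Zfp series carried H3K9me3 far more often than rotated peaks would place it there. Many of these genes encode DNA-binding repressors of retrotransposons and lie in clusters of recent duplicates. Of 391 Zfp genes, 231 (59.1%) had a replicated peak in the gene body or the 2 kb upstream, against a rotation mean of 111.2 genes, a 2.08-fold excess. Among the 246 clustered Zfp genes, those with another Zfp gene starting within 200 kb, 161 (65.4%) had a peak against a mean of 63.6. Both lists had a Benjamini-Hochberg adjusted permutation p of 0.0060 over the 12 lists. The members with the strongest peaks were Zfp810, Zfp991, Zfp180 and Zfp146. On Zfp180 (chromosome 7: 24081924 to 24107713) peaks covered 19.5 kb, or 70.2% of the gene and its upstream window, with 19.484 kb in replicate 1 and 16.1 kb in replicate 2. Zfp146 carried a single peak of 9383 bp at chromosome 7: 30159046 to 30168428, and 7.28 kb of its window lay under peaks in replicate 1 and 6.69 kb in replicate 2. The strongest peak of Zfp810 lay at chromosome 9: 22276576 to 22281042, mostly intron sequence at the 3′ end of the gene, with a signal value of 14.8. When only the 2 kb on either side of the transcription start site (TSS) were counted, 65 Zfp genes (rotation mean 35.6, 1.83-fold, adjusted permutation p = 0.082) and 47 clustered Zfp genes (mean 24.9, 1.89-fold, adjusted p = 0.12) had a peak. Neither passed the test, with the fold of all Zfp genes close to that in gene windows.

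Clustered Zfp genes had a peak more often in the last coding exon than at the TSS. The exon encoding the zinc finger array is found at the 3′ end. The rest of the gene body was not compared. Of the 230 clustered Zfp genes with more than 1 coding exon, 117 (50.9%) had a replicated peak in the last coding exon and 42 (18.3%) had one within 2 kb of the TSS. Peaks in the last coding exon alone were found in 83 genes and peaks at the TSS alone in 8 (exact two-sided sign test, p = 7.6e-17). Neighbouring genes are not independent, so the difference of 75 genes was also set against rotations, which gave a mean of -9.91 and a maximum of 4 (two-sided permutation test by rotation, p = 0.0020). The last exons had a median length of 1416 bp, shorter than the TSS window of 4001 bp. The counts were 149 against 86 in the list of replicate 1 and 111 against 56 in that of replicate 2.

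Imprinted genes, which are expressed from only the maternal or the paternal allele, carried a replicated peak at most members of their list. It was present at 37 of 40 members (92.5%), against a rotation mean of 14.0 genes and a maximum of 27 (2.63-fold, adjusted permutation p = 0.0060). The members without one were Dlk1, Rtl1 and Dio3, which lie in the same imprinted region of chromosome 12 as Meg3. At the TSS, 24 of 40 had a peak against a rotation mean of 3.63 (adjusted permutation p = 0.0080). The strongest peak, with a signal value of 11.1, lay in an intron of Grb10, an adaptor that restrains growth factor signalling, at chromosome 11: 12025275 to 12027249. The gene had 9.81 kb under peaks in replicate 1 and 3.91 kb in replicate 2. Mest, a paternally expressed gene of the hydrolase family, followed with a peak of 3780 bp at chromosome 6: 30736018 to 30739797 and a signal value of 10.3, and had 5.23 kb and 4.32 kb under peaks in replicates 1 and 2. At Meg3, a maternally expressed long noncoding RNA, a peak of 4340 bp at chromosome 12: 109537222 to 109541561 reached over the TSS. Gnas, the gene of the stimulatory G protein alpha subunit, and its antisense transcript Nespas shared a peak of 6721 bp over coding exon sequence at chromosome 2: 174294450 to 174301170.

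The other imprinted genes are given here by the annotation class of their strongest peak, which can be the promoter of another gene. Starts of noncoding genes did not count as promoters, and the strongest peaks of Airn, Nespas, Meg3 and Peg13 covered such starts. The peak shared by Igf2r, the receptor that clears IGF2, and its antisense silencer Airn lay over intron sequence of Igf2r at chromosome 17: 12741108 to 12743292, with a signal value of 8.11. Peg3 and Usp29 shared a peak of 4184 bp over their common promoter at chromosome 7: 6727075 to 6731258 (signal 7.95). Promoter peaks were also the strongest at Nnat, Cdkn1c, Magel2, Peg10, Snurf, Snrpn, Mkrn3, Nap1l5, Slc38a4, Blcap (signal 7.74), Sgce (7.27), Igf2 (6.30), Zrsr1 and Commd1 (5.93, a shared peak), Herc3 (5.72), and Mcts2 and H13 (5.09, also shared). The strongest peak lay in an intron at Inpp5f (8.72), Impact (8.33) and Plagl1 (7.72), in a UTR or noncoding exon at Kcnq1ot1 (7.98) and at Peg13 and Trappc9 (6.69, shared), and in a coding exon at Ndn (4.99) and Zim1 (4.43). At H19 the peak lay upstream of the gene in intergenic sequence, at chromosome 7: 142579759 to 142581491 (signal 5.68). Nnat, which encodes a small membrane protein, had 89.7% of its window under replicated peaks, with 3.57 kb in replicate 1 and 3.40 kb in replicate 2. The lowest signal values were those of Cdh15 (signal 3.48) and Rasgrf1 (signal 3.38), and Rasgrf1 had 2.43 kb under peaks in replicate 1 and 0.431 kb in replicate 2. Genes that overlap or share a promoter also share peaks, so the 37 genes are not 37 separate loci.

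Genes of the germline, which are silent in most somatic tissues, carried peaks mainly at their promoters. A replicated peak was found at 27 of 50 members against a rotation mean of 15.2 (1.77-fold, adjusted permutation p = 0.0060), and at the TSS of 21 against a mean of 3.58 (5.87-fold, adjusted p = 0.0080). Dazl, a germ cell regulator of translation, had the strongest, a peak of 1597 bp at chromosome 17: 50292865 to 50294461 with a signal value of 8.18, and 1.52 kb and 1.37 kb under peaks in replicates 1 and 2. Promoter peaks were also the strongest at Ddx4, a germ cell RNA helicase (signal 7.30, with 1.03 kb in replicate 1 and 0.907 kb in replicate 2), at Taf7l, a TFIID subunit of the testis (7.27), and at Mael, a factor of the piRNA pathway (6.49). Peaks were also present at the meiotic genes Sycp1, Sycp2, Sycp3, Stag3, Smc1b and Spo11. The 23 members without a replicated peak included the oocyte genes Figla, Nobox, Zp2 and Zp3. They also included the meiotic genes Syce1, Hormad1 and Meiob and the piRNA pathway genes Piwil2 and Piwil4. Kinds of germline genes were not compared.

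The clustered protocadherins, adhesion molecules that give neurons distinct surface identities, lay in 1 stretch of chromosome 18, much of which was densely covered in both replicates. Between the start sites of Pcdhac2 and Pcdhb1, coverage was sparse up to 37220000 and then rose. The bin from 37170001 to 37180000 had 1.08% of its bases under peaks in replicate 1 and 0% in replicate 2. That from 37250001 to 37260000 had 52.6% and 46.2%. Of 57 genes, 54 had a replicated peak in their window and at the TSS. The window count had a rotation mean of 26.6 (adjusted permutation p = 0.012) and the TSS count a rotation mean of 3.54 (15.2-fold, adjusted p = 0.0080). All 14 Pcdha and all 22 Pcdhb genes had a peak, as did 18 of the 21 Pcdhg genes. The members without one were Pcdhgc3, Pcdhgc4 and Pcdhgc5, at the 3′ end of the Pcdhg cluster. The strongest peaks were promoter peaks of the Pcdhg cluster at 37742577 to 37744085 (signal 14.5) and 37720860 to 37722454 (signal 14.3). Pcdhga1 had 107.4 kb under replicated peaks (59.0% of its window), with 106.4 kb in replicate 1 and 92.6 kb in replicate 2. Nested gene bodies in these clusters count the same peaks, so 9 of the 10 protein-coding genes with the most bases under peaks came from this stretch, the read-through models Gm42416 (384.6 kb), Gm37013 and Gm37388 followed by Pcdhga1, Pcdhga2 (102.6 kb), Pcdhga3 (97.7 kb), Pcdhgb1 (92.0 kb), Pcdhga4 (87.8 kb) and Pcdhgb2 (83.3 kb). The exception was Skint5, an immunoglobulin superfamily gene on chromosome 4, with 103.9 kb under replicated peaks, 123.4 kb in replicate 1 and 71.1 kb in replicate 2.

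**Figure D2:**
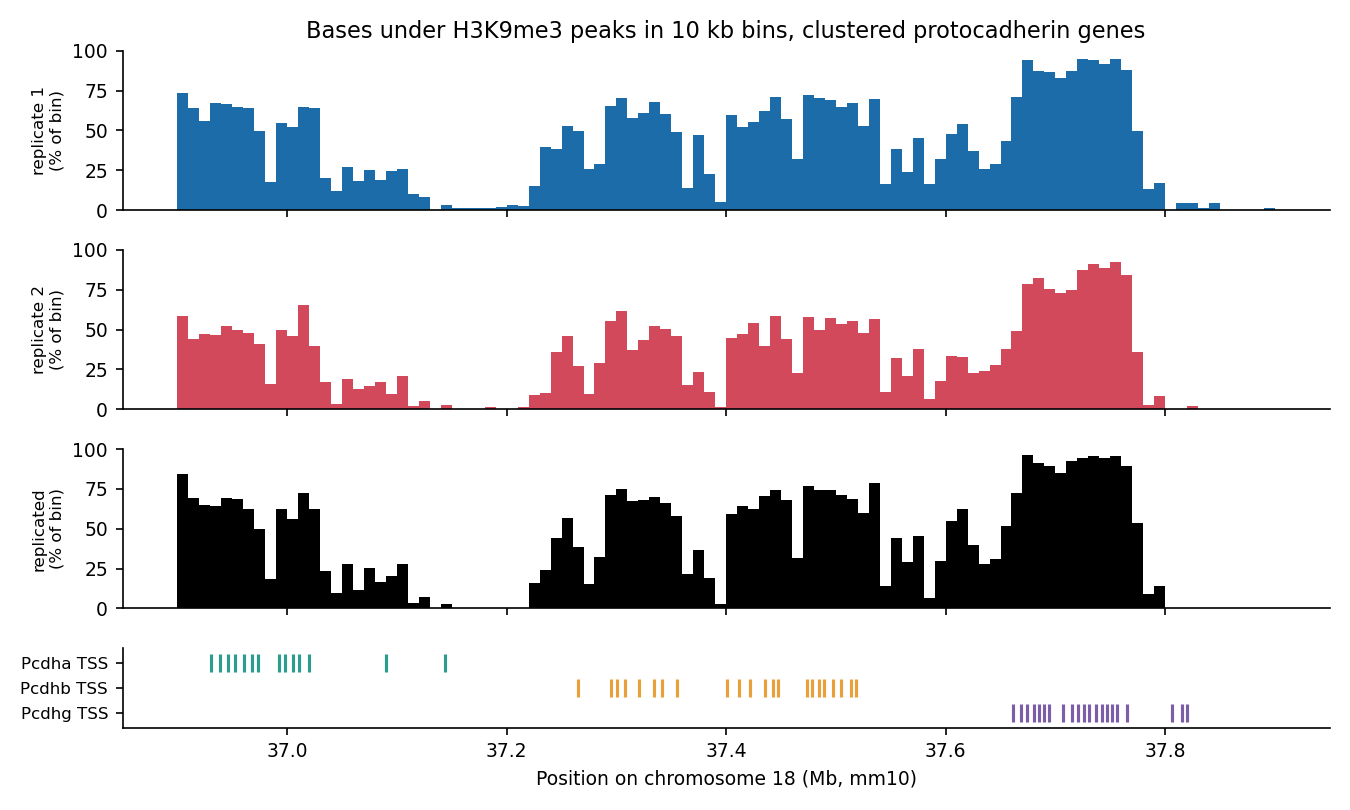
Share of each 10 kb bin (vertical axes, percent of bases) under H3K9me3 peaks of replicate 1, of replicate 2 and of the replicated list along the protocadherin clusters of chromosome 18 (horizontal axis, Mb in mm10), with the TSS of each Pcdha, Pcdhb and Pcdhg gene as a tick. Coverage is high over most start sites of the 3 clusters in both replicates and lower at that of Pcdhac1. It is near 0 at the start site of Pcdhac2 and at the last Pcdhg start sites, those of Pcdhgc3, Pcdhgc4 and Pcdhgc5.

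Chemosensory receptor genes formed 2 lists. Of 327 vomeronasal receptor genes, which detect pheromones, 135 (41.3%) had a replicated peak against a rotation mean of 77.7 (1.74-fold, adjusted permutation p = 0.012). Of 1094 olfactory receptor genes, 178 (16.3%) had one against a mean of 138.1, which did not pass the test (adjusted permutation p = 0.40), and the list of replicate 1 gave 380 without passing. Against random gene lists matched on length, which ignore gene clusters, both lists passed (adjusted permutation p = 0.00034 for each). The 2 lists were not tested against each other. Vmn1r69 had the highest signal of the vomeronasal genes (8.18), with 13.4 kb under peaks in replicate 1 and 7.56 kb in replicate 2, Vmn1r65 had 79.8% of its window under replicated peaks, Vmn2r60 had 59 peaks over 30.1 kb, and Vmn2r10 had 10 peaks and a signal value of 7.72. Among the olfactory receptors the highest signals were those of Olfr212 (7.50), Olfr161 (7.43), Olfr1349 (7.43) and Olfr1454 (6.81). The vomeronasal call rested on the replicated list: 186 genes had a peak in the list of replicate 1 (rotation mean 153.3, adjusted permutation p = 0.22), 146 in that of replicate 2 (mean 99.5, adjusted p = 0.072) and 187 in the pooled list (mean 146.9, adjusted p = 0.14).

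No replicated peak was found in any of the 39 Hox genes, which pattern the body axis and many of which are active in the hindbrain, but the rotation mean was only 4.14 genes and the list did not pass the test (adjusted permutation p = 0.16), although it did against random gene lists matched on length (adjusted permutation p = 0.012). The list of replicate 1 had a peak in 9 Hox genes (mean 10.6), that of replicate 2 in 4 (5.89) and the pooled list in 8. Hindbrain and neural progenitor genes had a peak at 8 of 50 members against a mean of 8.93 (adjusted permutation p = 0.92). These were Elavl3, Sox3, Pax3, Nkx6-1, Dll1, Lhx1, Lmx1a and Meis1. The strongest was a peak of 308 bp in an intron of Elavl3, a neuronal RNA-binding protein, with a signal value of 4.77. Sox3, a transcription factor of neural progenitors on chromosome X, had 1.66 kb under peaks in replicate 1 and 0.397 kb in replicate 2. Only Sox3 and Nkx6-1, a transcription factor of the ventral neural tube, had a replicated peak at the TSS. In the list of replicate 1 alone, 27 of the 50 genes had a peak against a mean of 18.7 (adjusted permutation p = 0.028), and in that of replicate 2 alone 10 did.

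The lists of other tissues and of housekeeping genes were not set apart from rotated peaks. Housekeeping genes had a peak at 3 of 30 members (rotation mean 5.48, adjusted permutation p = 0.40), which were Tbp, the TATA-binding protein (signal 4.997), Gusb, a lysosomal enzyme (4.77), and Hprt, an enzyme of purine salvage (4.54). In the list of replicate 1 they had 8, and in the pooled list 5, below the rotation mean of 11.9 (adjusted permutation p = 0.024). Blood, endothelial and mesenchyme genes, which mark other cell types the dissected tissue could hold, had a peak at 6 of 36 members (mean 9.11, adjusted permutation p = 0.40), at 18 in the list of replicate 1 and at 11 in that of replicate 2. The highest signals were at Flt1, a VEGF receptor (5.22), Col1a1, a fibrillar collagen (4.77), and the endothelial genes Pecam1 (4.32) and Tek (3.87), and none of the 36 had a peak at the TSS. Liver, muscle and skin genes had a peak at 7 of 35 (mean 6.57, adjusted permutation p = 0.99), and at 15 in the list of replicate 1. Cyp3a11, a hepatic cytochrome P450, stood out within that list with 25 peaks over 58.2% of its window, 13.3 kb in replicate 1 and 9.45 kb in replicate 2. Serpina1b and Serpina1a, the antitrypsin genes, and Flg, which encodes filaggrin, had signal values of 5.63, 4.32 and 4.32.

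**Figure D3:**
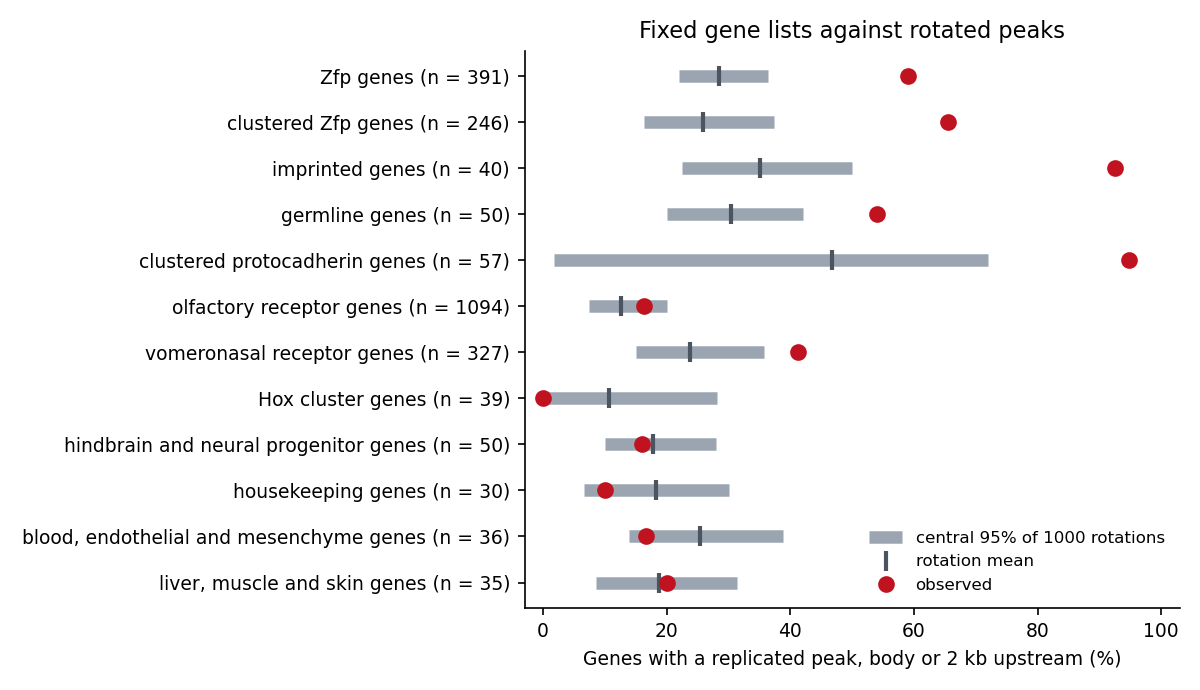
Share of the genes of each fixed list with a replicated peak in the gene body or the 2 kb upstream (circles, percent on the horizontal axis), with the mean (tick) and the central 95% (bar) of 1000 rotations of the peaks. The Zfp, clustered Zfp, imprinted, germline, clustered protocadherin and vomeronasal lists lie above the bar, and the other 6 lists lie within it.

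The 5 widest domains of H3K9me3 lay on chromosomes 7, 2 and 9. When replicated peaks at most 10 kb apart were merged, 23016 domains resulted, of which 14512 held a single peak. There were 126 domains of at least 100 kb, 34 of them on chromosome 7, and together they held 15685 peaks (24.7% of those on the main chromosomes). The list of replicate 1 gave 55409 domains, 203 of them of at least 100 kb, and a −log10 q of at least 5 left 9167 and 50. The widest, 843.8 kb at chromosome 7: 17594324 to 18438112, held the Ceacam adhesion genes and the pregnancy-specific glycoprotein genes Psg18 and Psg28. Peaks covered 45.3% of it in replicate 1 and 30.4% in replicate 2. The next on chromosome 7 were 689.0 kb over secretoglobin genes such as Scgb2b24 and Scgb1b27 (33385562 to 34074597) and 661.3 kb over vomeronasal receptor genes, Zik1 and Nlrp4b (10114719 to 10776053). A domain of 634.5 kb at chromosome 2: 36517366 to 37151839 covered olfactory receptor genes from Olfr342 to Olfr364-ps1, and one of 536.3 kb at chromosome 9: 36077832 to 36614162 held predicted genes such as Gm5916 and Gm7257. Domain counts followed the merging distance: domains of at least 100 kb numbered 1 at 1 kb and 792 at 50 kb.

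The replicated peak with the highest signal value (16.4) was an intergenic peak of 386 bp at chromosome 18: 3116714 to 3117099, 5.39 kb from Vmn1r238. It was followed by a promoter peak of 3715 bp at Trim71, an RNA-binding ubiquitin ligase of embryonic progenitors, at chromosome 9: 114511326 to 114515040 (signal 15.9), and by a peak of 5715 bp on an unlocalized scaffold of chromosome 4 (signal 15.4). The peak at chromosome 12: 20913702 to 20915841 lay in an intron of Zfp125 and 3110053B16Rik (signal 14.5). Its nearest protein-coding gene was Asap2 at 74.6 kb, so Zfp125 was not counted in the list of Zfp genes. The peak at chromosome 4: 147176424 to 147176609, in an intron of Zfp991, also had a signal value of 14.5. A peak of 8843 bp at chromosome 7: 24100286 to 24109128, in Zfp180, had 14.2. An intergenic peak at chromosome 5: 104583921 to 104584385 (signal 14.1) lay 61.3 kb from BC005561, the nearest protein-coding gene.

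Peak bases were displaced from introns towards exons and intergenic sequence. Introns held 31.0% of the bases of the replicated list against a rotation mean of 41.7%, intergenic sequence 57.5% against 50.1%, coding exons 2.59% against 1.32%, and UTRs with noncoding exons 4.78% against 3.37% (adjusted permutation p = 0.0025 for each). Promoters, the 2 kb on either side of the TSS of a protein-coding gene, held 4.15% against 3.50%. That share did not pass the test (adjusted permutation p = 0.064). The promoter share did pass in the list of replicate 1 (4.10%, adjusted permutation p = 0.0060) and in that of replicate 2 (4.32%, adjusted p = 0.010).

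The marked sequence was rich in guanine and cytosine. Peak bases had a GC content of 45.7% against a rotation mean of 42.1% (adjusted permutation p = 0.0060), and 41.7% over the called genome. The ratio of observed to expected CpG was 0.187 against 0.193 (adjusted permutation p = 0.057), and 35.5% of the bases were soft-masked as repeats or low complexity against 34.0% (adjusted p = 0.090). Neither passed the test. Over the called genome the CpG ratio was 0.190 and the soft-masked share 36.4%, both above the values of the peaks. Repeat sequence is hard to map with short reads, and how reads with several matches were treated was not given in the sources used here.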

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

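All tests of chromosome X in this part were chosen after the share of X peaks in each replicate was seen. The exception is the test of its spread along the chromosome, which was written before its result was known.

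On unplaced and unlocalized scaffolds, which entered none of the rotation tests, there were 437 replicated peaks over 305661 bases, with 719 peaks in replicate 1 and 497 in replicate 2. They are listed because they lie outside the tested chromosomes and exceed 3, the upper limit for an observed count of 0, which sets no expectation for scaffolds. The scaffold chrUn_JH584304 held 112 of them, and the strongest, with a signal value of 15.4, lay on a scaffold of chromosome 4. No explanation was tested.

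Replicate 1 had 6.12 times as many peaks on chromosome X as replicate 2, above all 19 autosomes (1.76 to 2.34). A longer list with weaker peaks in replicate 1 does not account for all of it: over all peaks the share of X peaks was 2.88 times higher in replicate 1 (6.93% against 2.41%), and with equal numbers of peaks by p-value rank it was 1.62 times higher. It was 2.56 times higher at a −log10 q of at least 2, 1.44 times among the top 10000 and 1.38 times at a −log10 q of at least 5. List length and rank thus enter the ratio. In replicate 1 the median −log10 q was 1.05 on X and 1.59 on autosomes. Of its X peaks 9.89% overlapped a peak of replicate 2, against 22.6% to 39.4% on the autosomes. The excess of X peaks was spread along the chromosome, since 94.1% of the 34 X bins of 5 Mb (32 bins) had a ratio above the autosomal median of 2.29. More X and less Y chromatin in replicate 1, as more female embryos in its pool could give, remains open: the ratio on Y was 1.38, below the autosomes, but its exact 95% interval of 1.08 to 1.78, from 155 and 112 peaks and for counting error only, reaches the lowest autosome. The sex ratio of each pool and the control used for each replicate are not given in the sources used here, and both stay among the candidate explanations.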

How the results depend on the processing

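Of 180 alternative values for 26 results, 154 kept their side of the threshold or stayed within 1.5 times, and 26 did not. A change of direction counted only where the original or the alternative value passed the threshold. The CpG ratio, for example, rose above its rotation mean at a −log10 q of at least 5 (0.198 against 0.193) and still counted as kept. The overlap of the replicates, the exon, intron and intergenic shares and the GC content kept their call under all alternatives run. So did the Zfp, imprinted, germline and protocadherin excess in gene windows (apart from Zfp at the TSS). The excess of Zfp genes with a peak in the last coding exon over those with one at the TSS also kept its call (differences of 30 to 95 genes). Leaving out 1 replicate gave 91746 to 195438 peaks, 32498 to 55409 domains and 148 to 203 domains of at least 100 kb. It gave 146 to 186 vomeronasal genes (calls lost in both), 10 to 27 hindbrain genes (direction reversed to an excess in replicate 1) and promoter shares of 4.10% to 4.32% (now past the threshold in both). With a −log10 q of at least 5 there were 22476 peaks, 9167 domains and 50 of at least 100 kb, by construction fewer, and the promoter share passed at 4.66%. Merging at 1 kb gave 38561 domains, 1 of at least 100 kb, and at 50 kb 12540, 792 of at least 100 kb, also by construction. The pooled list lost the vomeronasal call (187 genes) and gained a deficit of housekeeping genes (5), a promoter share of 3.99% and a soft-masked share of 35.7%. At the TSS, 65 Zfp (1.83-fold) and 47 clustered Zfp genes (1.89-fold) no longer passed, against 2.08-fold and 2.53-fold in gene windows. Against random gene lists, which ignore gene clusters, the 178 olfactory genes (adjusted permutation p = 0.00034) and the 0 Hox genes (adjusted p = 0.012) passed. Counts moved by more than 1.5 times without a changed call for Hox genes (9 in replicate 1, 4 in replicate 2, 8 pooled), blood, endothelial and mesenchyme genes (18, 11 and 16; 0 at the TSS), olfactory receptors (380 in replicate 1, 359 pooled, 97 at a −log10 q of at least 5), housekeeping genes (8 in replicate 1), liver, muscle and skin genes (15 in replicate 1, 4 at the TSS), hindbrain genes (21 pooled, 2 at a −log10 q of at least 5, at the TSS or with at least 500 bases), imprinted genes (24 at the TSS) and vomeronasal genes (84 at the TSS). Promoters of 1 kb and 5 kb held 2.20% and 10.01%, both past the threshold. Other causes were not tested. The list added after the data were seen, of replicated peaks that overlap both replicates, changed none of these calls. For the 78 values of named genes, 264 of 390 alternatives lay within the spread between the replicates, and 4 values fell to 0 bases, all at a −log10 q of at least 5. No paired analysis was possible because there is only 1 group. Unknown depth limits what the absence of a peak shows.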

Other observations

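The test of single-exon genes was chosen after the wide peaks at gene starts had been seen, and the genes named in the next paragraph were chosen after their values were seen. The tests of chromosome 7 and of the motif were written before their results were known.

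Outside the fixed lists, 79 protein-coding genes had a replicated peak of at least 1 kb within 500 bases of the TSS, and at all 79 genes the peak was covered in part in both replicates. The highest signal values were those of a peak of 1477 bp shared by 3110070M22Rik and Tmem267 (11.7), of peaks at Klf14 (2979 bp at chromosome 6: 30956076 to 30959054, 11.2), Gm10775 (2570 bp, 10.9) and Gm49394 (1536 bp, 10.1), and of one of 1586 bp at Rbmxl2 (9.31). Secretoglobin, cathepsin and Ceacam genes were also among the 79. These genes are not 79 separate loci, since some share a peak, and not all are apart from the loci of the lists. Gm38393 had the peak of Snrpn and Snurf, and Gm42416 and Gm37388 are read-through models of the protocadherin stretch. The Gm49394 peak started at 142669182 on chromosome 7, next to the Igf2 peak that ended at 142669026. Some of the 79 had a low signal value with a high −log10 q, such as Sfi1 (3.95 and 110.9) and Gm10800 (2.20 and 29.9). Peaks in regions prone to false signal were not filtered out, and such signal can recur in both replicates. No theme was tested for these genes.

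Gene families grouped by symbol stem, those of the fixed lists included, gave no call. Of 360 families of at least 8 protein-coding genes, 7 had more and 12 had fewer members with a peak than rotations at an unadjusted p under 0.05, and 18 would be expected by chance. The 7 were Zfp, Pcdhb, Vmn2r and Vmn1r, which belong to the fixed lists, and Defb, Nlrp and Smad. With 1000 rotations 1 family alone cannot go below an adjusted p of 0.719, so the test says little about single families.

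One hypothesis was that H3K9me3 marks the start of single-exon genes more often than that of genes with introns. The test used only genes outside the fixed lists and away from the receptor and Zfp clusters. Of these, 32 of 1989 genes with 1 coding exon (1.61%) had a peak of at least 500 bases at the TSS. Among the other genes, 164 of 16565 (0.99%) had one, a ratio of 1.63. The clustered protocadherin and imprinted genes, with a peak within 2 kb of the TSS at 54 of 57 and 24 of 40 members, were thus left out. The count of 32 was within the central 95% of rotations (mean 20.6, upper limit 33, permutation p = 0.080). The hypothesis thus did not pass its test among genes outside the lists, and single-exon genes of the lists were not tested. The other genes lay below their rotation mean of 195.9 (permutation p = 0.14). The ratio itself was not set against rotations, so the contrast between the groups has no p-value. Introns in UTRs were not considered in the split.

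The density of chromosome 7, 3.27 times the median of the other autosomes, may come from its clusters of Zfp, vomeronasal and olfactory receptor genes. Without the sequence within 100 kb of these genes on every chromosome, chromosome 7 still had 49.0 peaks per Mb, 2.47 times the median of 19.9 and above the highest other autosome (30.7). The sequence removed therefore accounts for only part of it. Only protein-coding members of the 3 lists were used. Pseudogenes and zinc finger genes with other names stayed in unless they lay within 100 kb of a member. The test cannot tell whether the rest comes from such genes. The Ceacam and secretoglobin genes are not among the gene classes that were removed, and other explanations were not tested.

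The strongest peaks of imprinted genes carried many copies of TGCCGC, the core motif of ZFP57, a zinc finger protein that maintains imprints. The 27 distinct peaks had a mean of 1.91 motifs per kb, against 0.513 in 10000 random sets of other replicated peaks matched on width and CpG ratio (upper limit of the central 95% 0.836, highest 1.22, permutation p = 0.00020, the smallest they can give). Only these peaks were scanned. The one of Kcnq1ot1 (143249684 to 143251620) lay inside the transcript, and a separate peak near its TSS was not scanned. At least 1 motif was found in 23 of the 27, with 14 at Gnas and Nespas, 12 at Mest and 10 at Snrpn and Snurf. None was found in the scanned peaks of Kcnq1ot1, Ndn and Igf2 or in that of Zrsr1 and Commd1. The excess of motifs is what ZFP57 binding as a source of H3K9me3 at these loci would give, as a hypothesis. The matching was not exact, with a median CpG ratio of 0.593 in the imprinted peaks and 0.544 in the matched ones. GC content and signal value were not matched. The motif is itself rich in G and C, so the test cannot separate it from GC content. The lists hold no measurement of ZFP57.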
